A study of Homo sapiens with 8 samples.

How the data were processed

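Total RNA was isolated with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The SKBR3 cells had been infected with pCDH-based and the HCC1954 cells with pGIPZ-based lentivirus, and stable clones had been selected with puromycin, per the labels' protocols. The submitters' processing notes name fastp, STAR, DESeq2 and the genome build hg38 without their roles or versions. The counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The authors deposited raw counts per gene as whole numbers for each library, with no normalization, and these counts were the only values used.

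The table holds 58870 genes, of which 35107 had a count in any library. Gene identifiers were matched without their version to GENCODE 29, with 58597 matches, and to a symbol table, with 58517 matches; 8 had no symbol. Coordinates are those of GENCODE 29 on GRCh38, the same assembly as hg38. Libraries held 17661273 to 18701318 counts. A zero over a group was given a floor of 3 counts, which covers counting error only, because the reads carry no molecular identifiers. The SD and SE values reflect the spread between libraries. Replicate pairs were compared before use: chi-square per degree of freedom was 3.09 and 1.66 in SKBR3 controls and overexpression and 114 and 83.2 in HCC1954 shControl and shSUFU, so every pair differed by more than sampling noise and all were kept as separate libraries.

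The tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined, except where the text says otherwise. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, one fit of the 4 groups over all 8 libraries, no covariates, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Genes were tested in a line if they passed edgeR's filterByExpr (minimum count 10, minimum total 15) in the 4 libraries of that line. The interaction was the SKBR3 difference, overexpression minus control, less the HCC1954 difference, shControl minus shSUFU. CPM values use the TMM-scaled library sizes. Overlaps between lines were compared with the product of the list lengths over the genes tested and with two-sided Fisher's exact tests. Both take every gene as equally likely to be called.

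Of 36 gene lists, 35 had at least 5 tested members and were tested in each line with camera from limma 3.58.1, with a preset correlation of 0.01, with an estimated correlation, and with fry. The list of blood cell markers had too few tested members. In HCC1954 8 lists were called by camera and in SKBR3 5 in the joint fit, and with an estimated correlation none held in either. That version of the test rests on the residual degrees of freedom, 4 in the joint fit and 2 in a line alone. A call lost there therefore cannot be laid to correlated genes rather than to few libraries. Lists not described individually were not called.

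Genes were named by rule: SUFU; the 10 rising and 10 falling genes with the largest fold among those past the threshold with at least 5 CPM in the higher group, a symbol and no overlap between groups; the core Hedgehog genes; up to 4 called members of each described list, or the 2 with the smallest p; up to 10 genes called in both lines in each sense; and the 5 genes with the smallest interaction p. Applying that rule also to the line-alone fits was decided after seeing the data.

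The scripts were tested on simulated counts drawn from the means and spread of each line, with 200 genes changed by 1.5, 2 or 4-fold. Genes were drawn independently with the line's own spread, which matches the line-alone fit by design. Variation between cultures beyond that of these libraries was not simulated. The spread differed strongly between the lines: the biological coefficient of variation was 3.20% for SKBR3 fitted alone, 29.0% for HCC1954 fitted alone and 20.6% in the joint fit. In simulated HCC1954 libraries 21 of 71 calls of the joint fit were false, against 2 of 35 in the line-alone fit, so the joint fit did not keep its nominal error rate there. In simulated SKBR3 libraries the joint fit recovered 2 of 67 genes changed 2-fold, against 77.6% in the line-alone fit. The joint fit was kept as the main one because it had been fixed beforehand, and the line-alone values stand beside it.

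The alternatives set beforehand were RLE and upper quartile scaling, no filter, a stricter filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, only the 4 libraries of the line, a replicate block, each library left out, and a 2-fold minimum. Added after seeing the data were DESeq2 on the libraries of a line, limma-voom with a weight per line, the robust prior of edgeR and a correction for GC content. For the line-alone fits, the gene list tests, a library left out, a replicate block, limma-voom and a 2-fold minimum were also added then.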

Results

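RNA was profiled in SKBR3 and HCC1954, human breast cancer cell lines that carry extra copies of the receptor gene ERBB2. SKBR3 cells carried a lentiviral vector for overexpression of SUFU, a negative regulator of Hedgehog signalling that binds the GLI transcription factors, or the empty vector. HCC1954 cells carried a lentiviral short hairpin RNA against SUFU (shSUFU) or the control vector (shControl). Each of the 4 groups had 2 libraries, 8 in all, with 17661273 to 18701318 gene counts per library. Mitochondrially encoded genes took 7.21% of the counts of shSUFU replicate 2 and between 4.34% and 4.72% in each of the other libraries. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

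The targeted gene was examined first. SUFU (ENSG00000107882.11, protein coding, chromosome 10, 102503987 to 102633535, plus strand, GRCh38) rose in SKBR3 from 22.5 ± 0.345 to 269 ± 3.86 CPM (counts scaled to library size, mean ± SD, n = 2 per group). The log2 fold change was 3.58 (SE 0.28, edgeR adjusted p = 0.0116 in the joint fit), with both overexpression libraries above both controls. With SKBR3 fitted alone it was also 3.58 (SE 0.06, edgeR adjusted p = 1.63e-26). In HCC1954, SUFU measured 18.4 and 29.2 CPM in the shControl libraries and 9.16 and 13.9 CPM in the shSUFU libraries. Both shSUFU values lay under both control values, but the 2.06-fold difference (log2 -1.04, SE 0.26) missed the threshold. The edgeR adjusted p was 0.0628 in the fit of all libraries and 0.254 with HCC1954 fitted alone. The test did not establish the knockdown of the target, and hairpin libraries are named by their label throughout. The miss does not argue against a knockdown either. In simulated HCC1954 libraries the joint fit recovered 9 of 67 genes changed 2-fold and the line-alone fit 0 of 67. The same limit holds for other changes near 2-fold in HCC1954. Over the alternatives of the joint fit the adjusted p ranged from 0.00805, with DESeq2 on all libraries, to 0.254; in edgeR it was 0.0308 without shControl replicate 1. In SKBR3 the joint-fit call of SUFU was lost without any one SKBR3 library, while its log2 fold change stayed between 3.56 and 3.60.

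**Figure D1:**
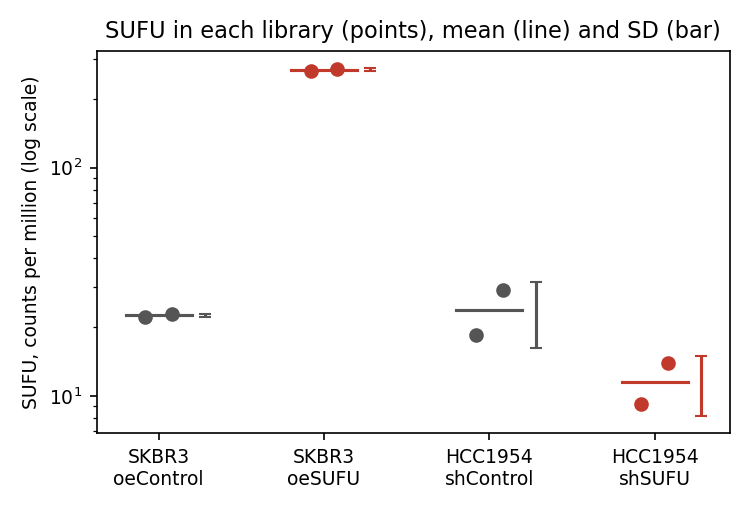
SUFU in CPM on a log axis, one point per library, with the mean as a line and the SD as a bar for each of the 4 groups. The SKBR3 overexpression libraries lie at 267 and 272 CPM against 22.3 and 22.8 in their controls, and the HCC1954 shSUFU libraries lie under their controls.

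Several core genes of the Hedgehog pathway had few or no counts. SMO, the receptor-coupled transducer of the pathway, had 0 counts in all 8 libraries. GLI2 had between 1 and 5 counts per library, and HHIP between 0 and 6. GLI1, a transcription factor that is also a direct target of the pathway, had 1 to 5 counts in 7 libraries and 56 counts (3.07 CPM) in shSUFU replicate 1, a rise that shSUFU replicate 2 did not share. PTCH1, a receptor and pathway target, measured 17.6 ± 0.480 CPM in SKBR3 controls and 13.7 ± 1.05 CPM with SUFU overexpression (n = 2). That difference had an edgeR adjusted p of 1 in the joint fit and 0.0416 with SKBR3 fitted alone, where PTCH1 lost its call without control replicate 1 (0.0860) and without overexpression replicate 1 (0.0722) or 2 (0.429); over the joint alternatives the adjusted p reached 1. In HCC1954, PTCH1 measured 19.5 ± 5.07 and 19.9 ± 0.604 CPM (edgeR adjusted p = 0.963), and GLI3 13.9 ± 4.02 and 27.2 ± 3.56 CPM (edgeR adjusted p = 0.0684, and 0.0111 for GLI3 without shControl replicate 2). Of 17 tested pathway components in HCC1954, GPR161 and BOC rose and HHAT fell in the joint fit (5 rose and 2 fell adjusted over the list alone), and none of them passed with the line fitted alone. Of 14 tested in SKBR3, 0 passed in the joint edgeR fit, and PTCH1 fell with the line alone (1 adjusted over the list alone). The list of pathway components had a camera adjusted p of 0.955 in SKBR3 and 0.178 in HCC1954, and 0.989 and 0.690 with an estimated correlation.

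The first comparison asked which genes differ between the overexpression and control libraries of SKBR3. These groups differ as separately selected cells too, so a difference is not by itself a response to SUFU. COL5A2, a fibrillar collagen chain (ENSG00000204262.13, chromosome 2, 189031896 to 189225312, GRCh38), fell 3.48-fold, from 278 ± 2.83 to 79.9 ± 1.16 CPM (n = 2; edgeR adjusted p = 0.0386). SUFU and COL5A2 were the 2 genes called among 14817 in the joint edgeR fit of all 8 libraries, with 148 genes at an unadjusted p under 0.05. With the 4 SKBR3 libraries fitted alone edgeR called 530 genes, of which 188 rose and 342 fell, mostly by small amounts: 44 changed at least 2-fold. The calls of the other SKBR3 genes named here come from that line-alone fit, and none of those genes passed in the joint fit.

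Among the genes that rose, GSTP1, a glutathione transferase, went from 23.0 ± 1.17 to 53.1 ± 4.69 CPM (edgeR adjusted p = 3.75e-11; 1.85e-24 to 1 over the alternatives of the joint fit), and DNAJA4, a co-chaperone, rose 2.40-fold to 8.47 ± 0.696 CPM. GPM6B rose 2.11-fold, and RAC2, a small GTPase, 1.83-fold. TRGC1 rose 2.30-fold, but it has a close copy in the same locus and its counts are uncertain. Among the genes that fell, EYA2, a transcriptional coactivator, fell by 1.47 on the log2 scale (SE 0.09) from 35.9 ± 3.04 CPM (edgeR adjusted p = 3.36e-11; 8.51e-24 to 1 over those alternatives). ALDH1A1, a retinaldehyde dehydrogenase, fell 2.51-fold, PTK7, a receptor-like pseudokinase, 2.32-fold, and KRT9, a keratin, 2.94-fold.

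Mesenchymal, TGF-beta and basal genes were among those that fell. Of 13 tested mesenchymal genes 4 fell (7 adjusted over the list alone) and none rose; among them fibronectin, FN1, went from 114 ± 4.80 to 68.2 ± 1.87 CPM and S100A4 from 348 ± 5.85 to 271 ± 6.70 CPM. Of 22 TGF-beta target genes 6 fell (7 adjusted over the list alone), among them THBS1, 1.49-fold, CDKN2B, 1.45-fold, PMEPA1, 1.23-fold, and the receptor gene TGFBR1, 1.25-fold. Of 18 basal mammary markers 5 fell (7 adjusted over the list alone), including KRT15, from 72.1 ± 3.88 to 48.0 ± 0.216 CPM, LAMA3, 1.39-fold, and SFN, 1.19-fold. In the line-alone list tests, added after the data were seen, the camera adjusted p of these lists was 1.02e-07, 1.02e-07 and 4.09e-07. Each call was lost with an estimated correlation (adjusted p = 0.472, 0.595 and 0.472). That correlation was -0.00421, 0.0610 and -0.0310, below the preset value for the mesenchymal and basal lists. Fry called the basal list (adjusted p = 0.00946) but not the mesenchymal and TGF-beta lists (fry adjusted p = 0.0985 and 0.122). In the joint fit the same lists had camera adjusted p of 0.00825, 0.0273 and 6.43e-06, without a member that passed singly (1 mesenchymal gene fell adjusted over the list alone), and none held with an estimated correlation (adjusted p = 0.373, 0.708 and 0.170).

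Of 14 Notch pathway genes 2 fell, NRARP by 1.69-fold and NOTCH3 by 1.14-fold (3 fell and 1 rose adjusted over the list alone), and of 13 stem cell associated genes 2 fell, ALDH1A1 and SOX4 (5 fell and 1 rose adjusted over the list alone). Of 49 cytosolic ribosomal protein genes 7 fell (12 fell and 1 rose adjusted over the list alone), such as RPS9 by 1.16-fold and RPL38 by 1.14-fold. Of 29 genes of ferroptosis and iron handling 5 fell, and 5 adjusted over the list alone, including the lipid peroxidase GPX4 by 1.13-fold and the ferritin chain FTL by 1.14-fold. The camera adjusted p of these 4 lists, all in the line-alone list tests added after the data were seen, was 0.0449, 0.000981, 0.00129 and 0.0449. None held with an estimated correlation (adjusted p = 0.595, 0.595, 0.642 and 0.642). At its main settings the joint fit did not call the ribosomal and ferroptosis lists. The joint fit called the Notch and stem cell lists downward too (camera adjusted p = 0.0429 and 0.00271, with an estimated correlation 0.708 and 0.373), with 0 members past the threshold, in edgeR, and 0 adjusted over the list alone. Of 20 luminal markers 2 rose and 5 fell (4 and 7 adjusted over the list alone); among them GATA3 and MUC1 fell 1.39-fold and 1.36-fold, while CA12 rose 1.16-fold, and the list was not called (camera adjusted p = 0.335, with an estimated correlation 0.751).

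Without any one SKBR3 library the joint edgeR fit called 0 genes, with 60 to 67 genes at an unadjusted p under 0.05, and COL5A2 had an adjusted p of at least 0.822 (2.37e-202 to 1 over the alternatives of the joint fit); with all libraries joint DESeq2 called 3 genes and limma-voom 2. The line-alone fit called 1085 without control replicate 2 and 221 or 207 without overexpression replicate 1 or 2. Of 68 named genes called in the line-alone fit, 63 and 61 stayed called without control replicate 1 or 2, and 42 and 46 without overexpression replicate 1 or 2. Of those named above, SFN, NOTCH3, RPL38, GPX4 and FTL lost their calls without either overexpression library (adjusted p up to 0.128, 0.205, 0.180, 0.442 and 0.282), RPL38 also without control replicate 1 (0.162) and FTL without control replicate 2 (0.0616). RPS9 and CA12 lost theirs without overexpression replicate 1 (0.134 and 0.175), and LAMA3 and NRARP without overexpression replicate 2 (0.0554 and 0.161). After the correction for GC content GPX4 and FTL were no longer called (adjusted p = 0.0583 and 0.0507), with log2 fold changes of -0.14 (SE 0.04) and -0.17 (SE 0.05) where they had been -0.17 (SE 0.05) and -0.19 (SE 0.05). In simulated SKBR3 libraries the joint fit recovered 0 of 67 genes changed 1.5-fold and 47 of 66 changed 4-fold. The line-alone fit recovered 73.1% and 98.5% of them, with 5.14% of its calls false. The simulation used the spread of these libraries, so it cannot show whether that spread understates variation between cultures. The groups did not overlap in 6696 genes, 45.2% of those tested, where chance gives 33.3%.

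The second comparison asked which genes differ between the shSUFU and shControl libraries of HCC1954. The groups also differ as separately selected cells, so a difference is not by itself a response to SUFU. S100A7 (ENSG00000143556.9, chromosome 1, 153457744 to 153460701, GRCh38), a calcium-binding protein of squamous epithelia, went from 3.39 ± 1.19 to 1330 ± 741 CPM (log2 8.61, SE 0.53, n = 2; edgeR adjusted p = 0.000229). The complement component C3 rose to 318 ± 102 CPM (log2 6.38, SE 0.39) and fibronectin, FN1, from 116 ± 1.75 to 1107 ± 191 CPM. IGFBP5, an insulin-like growth factor binding protein, fell from 385 ± 274 to 11.8 ± 8.68 CPM, and the mineralisation inhibitor MGP from 160 ± 54.2 to 13.8 ± 2.34 CPM. The joint edgeR fit called 672 of 15190 genes, 335 that rose and 337 that fell, and the line-alone fit called 237, 158 that rose and 79 that fell; 230 genes passed in both. In simulated HCC1954 libraries 29.6% of the calls of the joint fit were false, against 5.71% in the line-alone fit. Unless a sentence says otherwise, the genes named for HCC1954 passed in both fits. Single libraries moved some of these folds: the log2 fold change of S100A7 was 7.89 without shSUFU replicate 2, that of C3 6.98 without shControl replicate 1, and that of IGFBP5 -4.03 and -5.64 without shControl replicate 1 or 2 and -6.10 and -4.43 without shSUFU replicate 1 or 2.

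Other strong rises included the matrix metalloproteinase MMP3, at 0.420 ± 0.273 CPM in shControl (log2 7.13, SE 0.92), and the vitamin D hydroxylase CYP24A1, from 0.791 ± 0.724 to 54.6 ± 32.8 CPM. LRRC55 and LAIR1, the latter an inhibitory receptor of leukocytes, had 0 counts in both shControl libraries and reached 42.2 ± 7.90 and 11.6 ± 5.70 CPM (LAIR1 at 15.6 and 7.54 CPM). Against a floor of 3 counts over the control group these are at least 502-fold and 138-fold higher. S100A7A, SERPINB4 and SAA2 rose too, to 252 ± 30.6, 258 ± 170 and 20.7 ± 3.57 CPM, but each has a close paralog (S100A7, SERPINB3 and SAA1) and the split of reads between them is uncertain. Among the falling genes, the nuclear receptor NR2F1 went from 21.2 ± 2.86 to 1.13 ± 0.638 CPM, the tetraspanin TSPAN8 from 6.51 ± 2.47 to 0.110 ± 0.0756 CPM, GLYATL2 from 93.9 ± 35.3 to 6.92 ± 1.99 CPM, and the cornified envelope gene IVL from 18.9 ± 7.25 to 1.86 ± 0.0109 CPM. SAMD9 fell by 3.85 on the log2 scale (SE 0.86), with control libraries that differed widely, at 882 and 92.8 CPM. Without shControl replicate 1 its log2 fold change was -1.46 (edgeR adjusted p = 0.0523; 0.000569 to 0.196 over the alternatives of the joint fit for SAMD9), and SAMD9L, another falling gene, had controls at 126 and 18.3 CPM. The GC correction ended the line-alone calls of SAMD9 and SAMD9L (adjusted p = 0.141 and 0.0824), from -3.88 (SE 0.79) to -3.42 (SE 0.81) and from -4.02 (SE 0.73) to -3.70 (SE 0.75). Without shControl replicate 1 the log2 fold change was 7.58 for CYP24A1, 7.01 for S100A7A, 5.70 for SAA2 and -2.02 for SAMD9L, and without shControl replicate 2 it was 5.36, 10.05, 3.44 and -4.83, with MMP3 at 7.98 and SAMD9 at -4.73. Without shSUFU replicate 1 it was 7.86 for MMP3, 5.30 for CYP24A1, -6.68 for TSPAN8 and -4.95 for NR2F1, and without shSUFU replicate 2 it was 5.57 for MMP3 and 4.83 for SERPINB4.

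**Figure D2:**
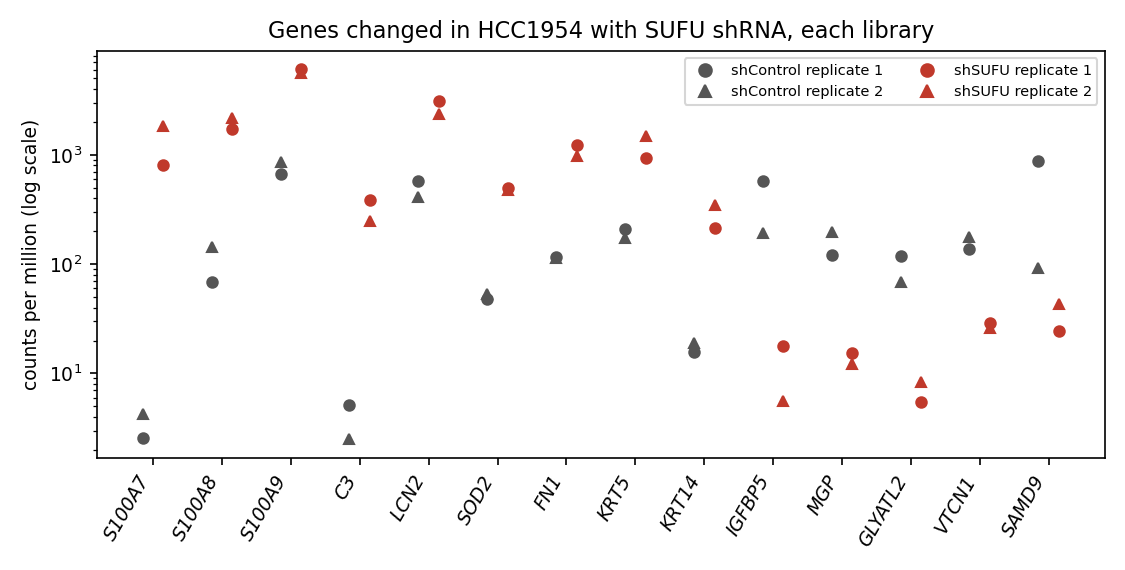
CPM on a log axis for 14 genes in each HCC1954 library, with controls in grey, SUFU hairpin in red, replicate 1 as circles and replicate 2 as triangles. In each gene both red points lie on the same side of both grey points. All 672 genes called in the joint fit are separated in this way, so the separation is no added evidence. SAMD9 shows the spread between the control libraries, 882 and 92.8 CPM.

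Of 27 tested NF-kB and cytokine genes 8 rose in the joint fit and none fell (12 rose adjusted over the list alone), among them the alarmins S100A8, from 107 ± 52.8 to 1947 ± 330 CPM, and S100A9, from 763 ± 141 to 5834 ± 329 CPM, and the siderophore-binding LCN2, from 496 ± 116 to 2741 ± 524 CPM. Of 20 immediate early and AP-1 genes 7 rose (10 adjusted over the list alone), with EGR1 at 21.4 ± 11.3 and 355 ± 292 CPM, FOSB at 5.04 ± 1.13 and 76.6 ± 71.6 CPM and the phosphatase gene DUSP1 at 5.89 ± 2.73 and 38.0 ± 12.7 CPM. Camera gave these lists adjusted p of 3.35e-11 and 8.94e-06, and neither call held with an estimated correlation (adjusted p = 0.570 and 0.160). The log2 fold change of S100A8 was 4.79 without shControl replicate 2 and that of EGR1 4.72 without shControl replicate 1. Without shSUFU replicate 1 or 2 it was 4.71 and 2.80 for EGR1 and 4.66 and 2.36 for FOSB. After a correction for GC content neither was called with the line alone (EGR1 adjusted p = 0.0550, FOSB 0.0735): the log2 fold change went from 4.03 (SE 0.60) to 3.94 (SE 0.72) and from 3.90 (SE 0.62) to 3.86 (SE 0.76).

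Of 23 mesenchymal genes 8 rose and 1 fell (10 and 2 adjusted over the list alone): after FN1, the collagen cross-linker LOXL2 rose by 2.41 on the log2 scale (SE 0.18), SPARC from 0.897 ± 0.467 to 11.1 ± 0.496 CPM (log2 4.25 without shControl replicate 2), and the integrin chain ITGA5 from 31.2 ± 4.05 to 99.2 ± 16.2 CPM. Of 23 basal mammary markers 4 rose and none fell (7 rose adjusted over the list alone), with KRT14 at 17.3 ± 2.19 and 282 ± 93.8 CPM, KRT5 2.66 higher on the log2 scale (SE 0.29), reaching 1204 ± 389 CPM, and COL17A1 at 3.46 ± 0.158 and 32.9 ± 10.1 CPM. The camera adjusted p was 1.29e-10 and 4.51e-06, and with an estimated correlation the adjusted p was 0.0571 and 0.0904. The self-contained fry test gave adjusted p of 0.000383 and 0.0141 in the joint fit and of 0.102 and 0.468 with the line alone. Of 17 luminal markers GATA3 fell 2.02-fold, in the joint fit alone (3 fell adjusted over the list alone; list camera adjusted p = 0.239, with an estimated correlation 0.690).

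Of 31 hypoxia and glycolysis genes 4 rose (9 adjusted over the list alone), including NDRG1, from 71.6 ± 4.67 to 409 ± 129 CPM, and, in the joint fit alone, the angiogenic factor VEGFA, from 228 ± 10.6 to 510 ± 179 CPM. The list's camera adjusted p was 7.92e-07, and 0.570 as the adjusted p with an estimated correlation. Cholesterol synthesis was the list called downward (camera adjusted p = 0.0146, with an estimated correlation adjusted p = 0.690), with 1 of 23 members called (2 adjusted over the list alone), MVD, which fell 1.70-fold in the joint fit alone. The Notch and DNA replication lists were called upward (camera adjusted p = 0.0267 and 0.0350, with an estimated correlation adjusted p = 0.668 and 0.774), each with 1 member called in the joint fit alone, NOTCH3 at 1.90-fold and CCNE1 at 1.78-fold (3 of 16 and 1 of 34 adjusted over the list alone). Of 39 interferon response genes 4 fell (6 adjusted over the list alone), among them IFIT2, 4.32-fold, and the list was not called (camera adjusted p = 0.178, with an estimated correlation 0.616). Of markers of other cell types, the monocyte gene CD14 rose from 0.506 ± 0.00574 to 8.26 ± 4.43 CPM (log2 3.32 without shSUFU replicate 2). Of 9 fibroblast and endothelial markers 1 rose (3 rose and 2 fell adjusted over the list alone), DCN, with 0 counts in shControl and 35 in shSUFU, at least 11.5-fold higher against the floor of 3 counts over the group. DCN lost its joint-fit call without any one library other than shControl replicate 2 (adjusted p up to 0.0868) and its line-alone call without either shSUFU library (up to 0.113) and after the GC correction (0.0539; log2 7.27, SE 1.21, against 7.12, SE 1.34), and the list was not called (camera adjusted p = 0.129, with an estimated correlation 0.668).

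The calls of S100A7, C3, FN1, S100A8, S100A9, LCN2, KRT14, KRT5, LOXL2, NDRG1, MGP, IGFBP5 and NR2F1 held under every alternative run for single genes, in the joint and the line-alone fits. Of 75 named genes called in the joint fit, 33 held under all of its alternatives. Of 59 called in the line-alone fit, 56 and 59 stayed called without shControl replicate 1 or 2, 41 and 45 without shSUFU replicate 1 or 2, and 44 after a correction for GC content. DUSP1 and ITGA5 lost their line-alone calls without shSUFU replicate 1 (adjusted p = 0.0654 and 0.132), and ANO1 without either shSUFU library (up to 0.146). In the joint fit the calls of MMP3 and FOSB were lost without shControl replicate 1 (adjusted p = 0.0672 and 0.0765), and those of TSPAN8 and MMP13 without shSUFU replicate 1 (0.0504 and 0.0544) or 2 (0.0545 and 0.0643). Of the joint fits that leave out a library, SAMD9, SAMD9L and HHAT passed only in the one without shControl replicate 2, with an adjusted p of up to 0.166, 0.150 and 0.116. In the line-alone fit SAMD9 and IFIT2 lost their calls without either shSUFU library (up to 0.165 and 0.131) and SAMD9L without shSUFU replicate 1 (0.111). IFIT2 lost its joint-fit call without any HCC1954 library but shControl replicate 2 and without either overexpression library, with an adjusted p of 0.0618 or more. Of the genes called in the joint fit alone, those that follow each lost their call without any one SKBR3 library and without at least 1 HCC1954 library, with an adjusted p of up to 0.0879 for GPR161, 0.0968 for BOC, 0.109 for MVD, 0.105 for NOTCH3, 0.116 for CCNE1, 0.0973 for VEGFA and 0.0998 for GATA3. The joint fit called between 208 and 230 genes without any one SKBR3 library, none of which enters this contrast, and 3532 without shControl replicate 2. The line-alone fit called 421 and 1333 without shControl replicate 1 or 2, and 117 and 125 without shSUFU replicate 1 or 2, the mitochondria-rich library being the latter. Rising genes made up 49.9% of the calls of the joint fit and 66.7% of those of the line-alone fit. The groups did not overlap in 6355 genes, 41.8% of those tested, where chance gives 33.3%.

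The third comparison set both perturbations side by side over the 13215 genes tested in both lines. Fibronectin, the metalloproteinase MMP13, the imprinted RNA H19 and the water channel AQP3 fell with SUFU overexpression in SKBR3 and rose with the SUFU hairpin in HCC1954. H19 fell 1.36-fold from 2426 ± 31.3 CPM in SKBR3 and rose from 2.35 ± 1.32 to 40.2 ± 6.66 CPM in HCC1954 (log2 4.80 without shControl replicate 2). AQP3 went from 390 ± 0.231 to 293 ± 0.884 CPM and from 41.2 ± 6.53 to 151 ± 2.35 CPM. VTCN1, an inhibitory ligand of T cells, rose 1.18-fold with overexpression and fell 5.78-fold with the hairpin. IGFBP5, GLYATL2, ANO1, IVL and CEACAM6 fell in both. After the GC correction MMP13 and CEACAM6 were not called in HCC1954 alone (adjusted p = 0.0550 and 0.103), at a log2 fold change of 4.39 (SE 0.80) against 4.25 (SE 0.67) before for MMP13, which was 3.45 and 6.16 without shControl replicate 1 or 2, and of -2.16 (SE 0.46) against -2.12 (SE 0.45) for CEACAM6. In SKBR3, MMP13 lost its call without overexpression replicate 2 (adjusted p = 0.137) and VTCN1 without overexpression replicate 1 (0.153); in HCC1954, CEACAM6 lost its line-alone call without shSUFU replicate 1 (0.213).

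These genes were called with each line fitted alone: 10 in opposite directions and 10 in the same direction. These numbers became 6 and 8 or 7 and 6 without overexpression replicate 1 or 2, 19 and 13 or 51 and 29 without shControl replicate 1 or 2, and 10 and 6 without shSUFU replicate 2; with the GC correction in HCC1954 they were 6 and 5. Genes that fell with overexpression and rose with the hairpin numbered 8, where independent lists would share 1.95 (Fisher's exact test, two-sided, p = 0.000730). The reverse held for 2 against 0.599 (p = 0.121 in the exact test). Genes that fell in both numbered 8 against 1.12 (exact p = 1.30e-05), and 2 rose in both against 1.05 (exact p = 0.282). In the joint fit 0 genes were called in both lines, with 148 and 3502 genes at an unadjusted p under 0.05 in SKBR3 and HCC1954; joint DESeq2 called 1 in opposite directions and none in the same direction, and joint limma-voom called 0 of either kind. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of -0.0206 and a Spearman correlation of -0.0400.

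**Figure D3:**
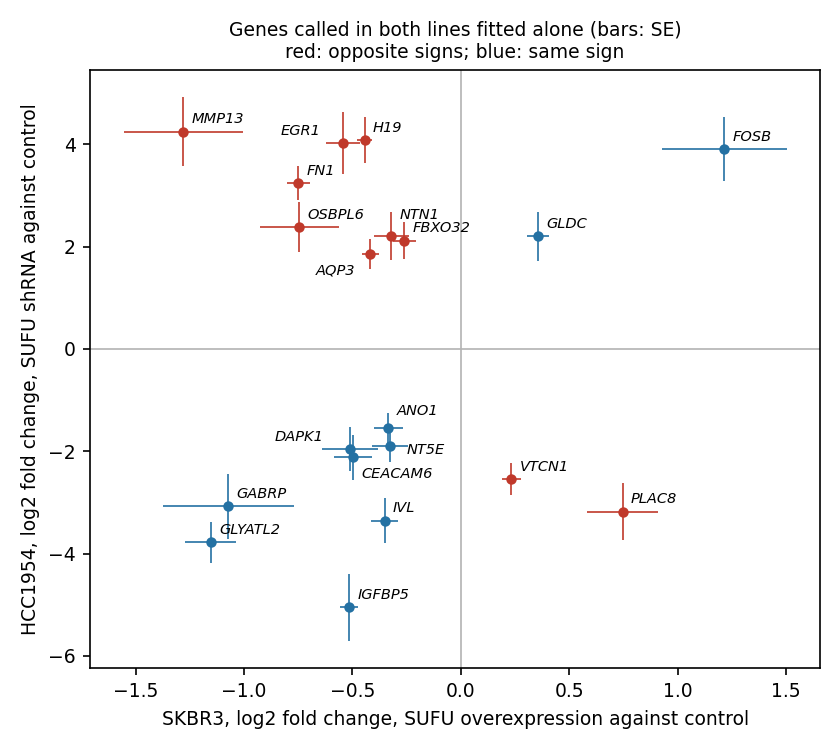
Log2 fold changes of the 20 genes called in both lines fitted alone, SKBR3 with SUFU overexpression on the x axis and HCC1954 with SUFU shRNA on the y axis, with SE bars. The 10 red genes have opposite signs and the 10 blue genes the same sign, and each gene lies further from 0 on the HCC1954 axis.

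The SKBR3 difference, overexpression minus control, differed from the HCC1954 difference, shControl minus shSUFU, in 60 of 13215 genes (edgeR interaction test, joint fit). In simulated HCC1954 libraries 29.6% of the calls of the joint fit were false, and interaction calls were not simulated. Lower SUFU in the shSUFU libraries was itself not established. SOD2, the mitochondrial superoxide dismutase, measured 110 ± 2.82 and 105 ± 0.974 CPM in SKBR3 control and overexpression libraries, and 50.3 ± 3.44 and 489 ± 12.5 CPM in HCC1954 shControl and shSUFU libraries. The ribonuclease gene ZC3H12A measured 29.1 ± 0.601 and 28.6 ± 1.12 CPM in SKBR3 and 21.2 ± 3.30 and 185 ± 20.9 CPM in HCC1954. Line, vector and kind of perturbation change together, so the test does not separate them. The edgeR count of 60 became 0 without either SKBR3 control library, with 751 and 754 genes at an unadjusted p under 0.05; joint DESeq2 and limma-voom on all libraries called 286 and 46. It was 9 and 10 without overexpression replicate 1 or 2, and 139 and 1348 without shControl replicate 1 or 2.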

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

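The interaction test was fixed beforehand, and the tests of library pairs, SKBR3 carry-over, GC content, control libraries and standard errors were chosen after the result was seen. The SKBR3 difference, overexpression minus control, differed from the HCC1954 difference, shControl minus shSUFU, in 60 genes by the edgeR interaction test. The 5 genes with the smallest interaction p were SOD2, with a log2 difference between the effects of 3.21, S100A7 with 8.28, ZC3H12A with 3.10, MOB3B with 3.03 and S100A9 with 2.83. In SKBR3 their log2 fold changes were small (SOD2 -0.07, S100A7 -0.33, ZC3H12A -0.03, MOB3B -0.10, S100A9 -0.11), and in HCC1954 the hairpin libraries were higher for each. The line, the vector and the kind of perturbation change together, so a biological difference between the lines stays open and untested.

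For the genes called in HCC1954, an effect present only in the mitochondria-rich library shSUFU replicate 2 is argued against, since the log2 differences of library pairs that share no library correlated at 0.420 and 0.392 across genes. SKBR3 RNA in the hairpin libraries, which the rise of H19 could have come from, is argued against too: 3 genes above 100 CPM in SKBR3 and near zero in shControl, among them ATP2A3 at 663 CPM, reached a median of 0% of their SKBR3 level in shSUFU, where H19 would need 1.81%. A GC-content trend as the whole source is argued against, because 60.3% of the line-alone calls stayed called after correction (146 genes called in all) and the 94 that were lost kept a median of 97.2% of their log2 fold change (lower quartile 93.9%); why these calls ended was not tested. Variation among control libraries along the same axis remains a candidate explanation for part of the change: the difference between the shControl libraries correlated with the hairpin effect at 0.330 across genes (0.0216 in SKBR3). The bound for that value was set after a preliminary value was known, and unequal noise in the 2 controls would raise it as well, so the share of such variation stays open. Differences between separately selected cell populations, and effects of the hairpin on other targets, change together with this comparison. They were not tested and stay open.

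The gap between 2 and 530 calls in SKBR3 was weighed next. The standard error of the SKBR3 fold change was 2.39 times as large in the joint fit as in the line-alone fit in the median, as it would be if the spread of HCC1954 entered the shared estimate. A GC-content trend as the whole source of the line-alone calls is argued against, since 91.3% stayed called after correction. Differences between separately selected cell populations, unrelated to SUFU, were not tested and stay open.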

How the results depend on the processing

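Left-out libraries leave an arm with 1 library, which is assumed to vary like the other groups. The labels give the replicates as numbers only and do not say whether equal numbers share a batch. Same-numbered deviations correlated at 0.0342 in SKBR3 and 0.0366 in HCC1954 over all tested genes. A batch that moves part of the genes is not excluded by that. With the replicate block the joint fit called 1 gene in SKBR3, 155 in HCC1954 and 13 in the interaction, and the line-alone fits called 874 and 322. Where no cause is given, the cause was not tested.

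For SKBR3 the count of 2 became 530 with the line alone, and 207 with DESeq2 on the line and 57 with limma-voom weighted by line, both chosen after the data were seen; leaving out a library gave 0 to 2. For HCC1954 the count of 672 became 1357 with joint DESeq2, 237 with the line alone and 133 with limma-voom weighted by line; leaving out a library gave 208 to 3532. RLE scaling gave 656 and upper quartile scaling 654 genes, 653 and 639 of them shared with the 672. The line-alone counts ranged from 207 to 1085 in SKBR3 and from 117 to 1333 in HCC1954 with a library left out; 44 SKBR3 calls were at least 2-fold, and the GC correction left 146 calls in HCC1954.

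The interaction count of 60 became 131 without the filter and 286 with DESeq2, and 0 to 1348 with a library left out. In opposite directions 1 gene was called in both lines without the filter and 1 with joint DESeq2. Each line alone gave 10, DESeq2 on each line 8 and weighted limma-voom 3. In the same direction the last 3 of these fits gave 10, 10 and 1. The correlation of fold changes was -0.0659 with the stricter filter, which tests fewer genes, and -0.0467 to 0.0148 with a library left out. SUFU in HCC1954 passed with a log2 fold change of -1.04 without the filter and -1.03 with joint DESeq2, and ranged from -1.38 to -0.70 with a library left out; SUFU in SKBR3 ranged from 3.56 to 3.60. The lists called in SKBR3 went from 5 to 0 with an estimated correlation and 0 with fry, and from 1 to 6 with a library left out; in HCC1954 8 became 0 and 3.

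Of the named-gene results, 2493 kept their side of the threshold, 285 lost it and 127 gained it, and none reversed; of the list results 139 kept theirs and 43 lost it. Apart from SUFU, 1 named SKBR3 gene was called in the joint fit, so for the others keeping their side meant staying uncalled. A reversal was counted only where the gene was called in the main or the alternative fit. Depth of 17661273 to 18701318 counts limits genes such as GLI2 and HHIP, with at most 6 counts in any library.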

Other observations

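The permutation tests of genes called in both lines were chosen after the result was seen. SAT1, the rate-limiting enzyme of polyamine breakdown, rose from 340 ± 134 to 1164 ± 289 CPM with the hairpin (n = 2; edgeR adjusted p = 0.0145 in the joint fit and 0.0372 with the line alone; 8.40e-08 to 0.0549 over the alternatives of the joint fit, the latter for SAT1 without shSUFU replicate 1, where the line-alone value was 0.141), and the ubiquitin ligase gene FBXO32 rose from 42.6 ± 20.1 to 186 ± 9.13 CPM. Of 23 YAP/TAZ target genes 4 rose and 2 fell in the joint fit (5 and 2 adjusted over the list alone): NUAK2 rose by 1.77 on the log2 scale (SE 0.23), while ANKRD1 fell 13.5-fold, from 4.57 ± 3.79 to 0.332 ± 0.148 CPM, and the list was not called (camera adjusted p = 0.205, with an estimated correlation 0.781). The cell-adhesion gene CEACAM6 fell from 832 ± 505 to 194 ± 73.4 CPM, with the shControl libraries at 1190 and 475 CPM. ANKRD1 and CEACAM6 lost their joint-fit calls without any one library other than shControl replicate 2 (adjusted p up to 0.103 and 0.117). The log2 fold change of ANKRD1 was -2.49 and -4.44 without shControl replicate 1 or 2, and that of CEACAM6 -1.29 without shControl replicate 1. NUAK2 lost its line-alone call without either shSUFU library (up to 0.172), and ANKRD1 without either of these or shControl replicate 1 (0.0754 or more). After the GC correction SAT1 and ANKRD1 were not called with the line alone (0.0774 and 0.0996), with log2 fold changes of 1.84 (SE 0.37) against 1.76 (SE 0.37) before and of -3.69 (SE 0.79) against -3.78 (SE 0.76).

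The genes called in both lines raise the hypothesis that they respond reciprocally to SUFU level. With edgeR on each line 10 genes moved in the same direction, where permuted calls give 2.16 (permutation test over 100000 draws that treat genes as independent, which they are not, p = 0.00007), and 10 in opposite directions, where they give 2.55 (p = 0.0003). The draws also take every gene as equally likely to be called, whatever its level or spread. Genes that are easier to call in both lines would raise both counts, so an excess does not by itself show a shared response. After the GC correction in HCC1954 the edgeR counts were 5 and 6, and DESeq2 on each line gave 10 in the same direction and 8 in opposite directions (permutation p = 0.00007 and 0.00225). With limma-voom weighted by line 1 gene moved in the same direction against 0.109 (permutation p = 0.104) and 3 in opposite directions against 0.168 (p = 0.00054). A reciprocal response forbids a change in the same direction in both lines. The 10 genes called so with edgeR, and the 10 with DESeq2, argue against it as the whole account of the genes called in both lines. This needs no excess over permuted calls, but it needs the calls to be true in both lines. In the weighted fit, with few calls, 1 gene moved that way and the same-direction excess did not pass. Whether the genes called in opposite directions respond reciprocally to SUFU level stays open, as does a set of genes that could move under either perturbation.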
